A study of Homo sapiens with 12 samples.

How the data were processed

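RNA from A375 cells, a human melanoma line, had been hybridised to 12 Affymetrix arrays in 6 groups of 2. Total RNA and RNA associated with polysomes were each taken from cells given DMSO for 2 h, IFN-gamma for 24 h, or IFN-gamma for 24 h together with silvestrol for 2 h. RNA was extracted with Trizol and labelled with biotin by the Affymetrix protocol, per the labels' protocols. The deposited table gave 1 intensity per transcript cluster and array on a linear scale, from 3.91 to 960000. The software, background correction, summarization and normalization between arrays are not given in the sources used here, and neither is the genome build of the array. The medians of the arrays lay between 17.7 and 18.9, so the values were taken as already scaled between arrays, and folds depend on that unstated scale. No detection calls were used, so a fold over a group near the lowest intensities measures signal over background.

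The table held 65535 transcript clusters, and their identifiers carried chromosome prefixes from 1 to 9 with 1729 clusters of the last one. It therefore covered part of the genome: of the protein-coding genes of a reference gene table (GRCh38.p14 RefSeq, used for names alone), 82.7% to 89.8% were measured on each of chromosomes 1 to 8 and 17.4% on chromosome 9. A gene symbol was paired with 16549 clusters, 16130 of them with 1 symbol and 419 with several, and 48986 clusters had none. Of the clusters with 1 symbol, 10777 matched the reference by Entrez identifier, 4991 by symbol and 179 by an older symbol, while 183 kept the symbol given. Each gene was represented by its cluster with the highest mean over all 12 arrays, which left 15196 genes, 7823 of them protein-coding, and 698 had more than 1 cluster. For 52 genes the cluster had the same 12 values as another cluster, as for C4A and C4B, and such genes cannot be told apart.

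Intensities were transformed as log2(value + 1). A linear model with 1 mean per group was fitted to all genes and all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend and not robust), which left 6 residual degrees of freedom. The prior had 5.68 degrees of freedom and an SD of 0.293 on the log2 scale, and the median residual SD was 0.301. The number of arrays limits the precision. Moderated t statistics were two-sided and adjusted by Benjamini-Hochberg over all genes within each of 7 comparisons, with a threshold of 0.05. The comparisons were IFN-gamma against DMSO and silvestrol with IFN-gamma against IFN-gamma, each in total and in polysomal RNA. The difference of each effect between the fractions and polysomal against total RNA in DMSO cells completed them. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

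Before the data were examined, 30 gene lists of 830 members were written down on interferon signalling, antigen presentation, GTPases together with enzymes of tryptophan metabolism, translation, stress responses, cell cycle, melanoma state and markers of cells that A375 cultures should lack. Of these members 376 were measured, 355 distinct genes, since some genes stand in more than 1 list. The 27 lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over lists within a comparison, with an estimated correlation and with limma's fry beside it. Median changes are given without subtraction of the median of all genes. The genes named were also chosen by a rule set beforehand. It took 22 preset genes, of which 15 were measured, and the 8 largest rises and 8 largest falls among called genes whose arrays did not overlap between the groups. It skipped unnamed loci and pseudogenes, and added up to 4 members with the smallest p of each list. Where no gene passed, the 4 genes with the smallest p were named.

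The procedure was tested on simulated data with the real means and spreads, 200 changed genes and 10 draws. For IFN-gamma in total RNA over 15196 genes it recovered 20.7%, 94.8% and 99.7% of changes of 1, 2 and 3 on the log2 scale, with 6.6 false calls per draw. For the difference of the silvestrol effects between fractions it recovered 3.4%, 62.2% and 97.4%, with 8 false calls per draw. In list tests without an effect 1 of 270 passed, and a shifted list was found in 10 of 10 draws. Simulated genes varied independently, so these draws do not show how often lists pass falsely where genes vary together.

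Alternatives tried were quantile normalization over all arrays or within each fraction, median centring, 2 filters on dim genes, and all clusters or the mean of a gene's clusters as the unit. Further ones were an intensity trend with robust spread, array quality weights, the arrays of the comparison alone, the replicate number as a block, each treatment and number as a block for the differences between fractions, a pseudocount of 16, a minimum log2 change of 1, and each array left out in turn. Comparisons of IFN-gamma plus silvestrol with DMSO were added after the data were seen. The IFN-gamma arrays enter both the IFN-gamma and the silvestrol comparison of a fraction, so genes induced in 1 fraction were followed in the silvestrol comparison of the other fraction. The time of treatment differed between DMSO and IFN-gamma, so the IFN-gamma effect cannot be told apart from 2 h against 24 h of treatment. Nothing in the labels says that the 2 replicates of a group were separate cultures, so p-values measure only the spread between these samples. Some preset genes and list members are not analysed here.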

Results

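A375 is a human melanoma cell line. IFN-gamma is a cytokine of T cells and natural killer cells that switches on genes of antigen presentation and cell defence, among them CD274, which encodes the immune checkpoint ligand PD-L1. Silvestrol is a plant-derived inhibitor of eIF4A, the RNA helicase of the eIF4F complex that prepares capped mRNAs for ribosome binding. Polysomes are mRNAs carrying several ribosomes, so polysomal RNA samples the mRNAs being translated and total RNA samples all of them. The series held 12 arrays, 2 for each of 3 treatments in each of the 2 fractions, and 15196 genes were compared. Replicate arrays correlated at 0.987 to 0.992. The polysomal IFN-gamma arrays stood apart in their upper range: their 99th percentile intensities were 24799.9 and 27570.6, against 30362.8 to 37995.9 in the other 10 arrays. Errors below are standard errors (SE) of a log2 fold change between groups of 2 arrays unless stated otherwise, and adjusted p-values come from limma.

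The first question was which RNAs IFN-gamma changed in total RNA. IFN-gamma raised the classical interferon-response genes, from the transcription factor IRF1 to the machinery of antigen presentation. IDO1, a tryptophan-degrading enzyme that restrains T cells, rose by 12.79 ± 0.44 on the log2 scale (adjusted p = 9.2e-09). IRF1 rose by 9.33 ± 0.27 (adjusted p = 6.8e-09), which was 645-fold, and CD274 rose by 6.28 ± 0.32 (adjusted p = 4.1e-07), which was 77.5-fold. The mean CD274 intensity was 131.5 ± 8.49 in DMSO cells and 10760 ± 4567 in IFN-gamma cells (SD, n = 2 each). In all, 152 genes rose and 32 fell.

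After IDO1 and IRF1 the largest rises were in the T cell chemokine CXCL10 (9.19 ± 0.54), the defence GTPases GBP1 (9.01 ± 0.29), GBP2 (6.84 ± 0.28) and GBP5 (6.30 ± 0.96), the peptide transporter TAP1 (7.95 ± 0.25) and cathepsin S, CTSS (7.35 ± 0.40). Their adjusted p-values ran from 6.8e-09 for GBP1 and TAP1 to 0.0048 for GBP5. PDCD1LG2, which encodes the second PD-1 ligand PD-L2, rose by 3.15 ± 0.35 (adjusted p = 0.00032), and MCL1, an anti-apoptotic BCL2 relative, rose by 2.20 ± 0.26 (adjusted p = 0.00051). The deepest falls were in GASK1B (-2.59 ± 0.35), LONRF2 (-2.47 ± 0.49), the retinoid receptor RXRG (-2.18 ± 0.41) and TBC1D7, a subunit of the TSC complex (-2.18 ± 0.40). CA8 (-1.94 ± 0.34), ZNF330 (-1.84 ± 0.37), the interleukin-6 receptor IL6R (-1.68 ± 0.35) and the neurofilament NEFL (-1.65 ± 0.31) also fell. Adjusted p-values of the genes that fell lay between 0.0018 for GASK1B and 0.039 for IL6R. The melanocyte transcription factor MITF (-1.58 ± 0.35, adjusted p = 0.055) and MYC (-1.91 ± 0.46, adjusted p = 0.094) did not pass. Without total DMSO replicate 2 MYC passed, at -2.71 (adjusted p = 0.0093, range over its 23 alternatives 0.0093 to 0.642). The kinases JAK1 (-0.13 ± 0.33, adjusted p = 0.964) and JAK2 (1.09 ± 0.31, adjusted p = 0.171), the receptor IFNGR1 (-0.18 ± 0.36, adjusted p = 0.95), the cap-binding factor EIF4E (-0.56 ± 0.38, adjusted p = 0.739) and the scaffold EIF4G1 (-0.12 ± 0.41, adjusted p = 0.975) did not pass either.

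**Figure D1:**
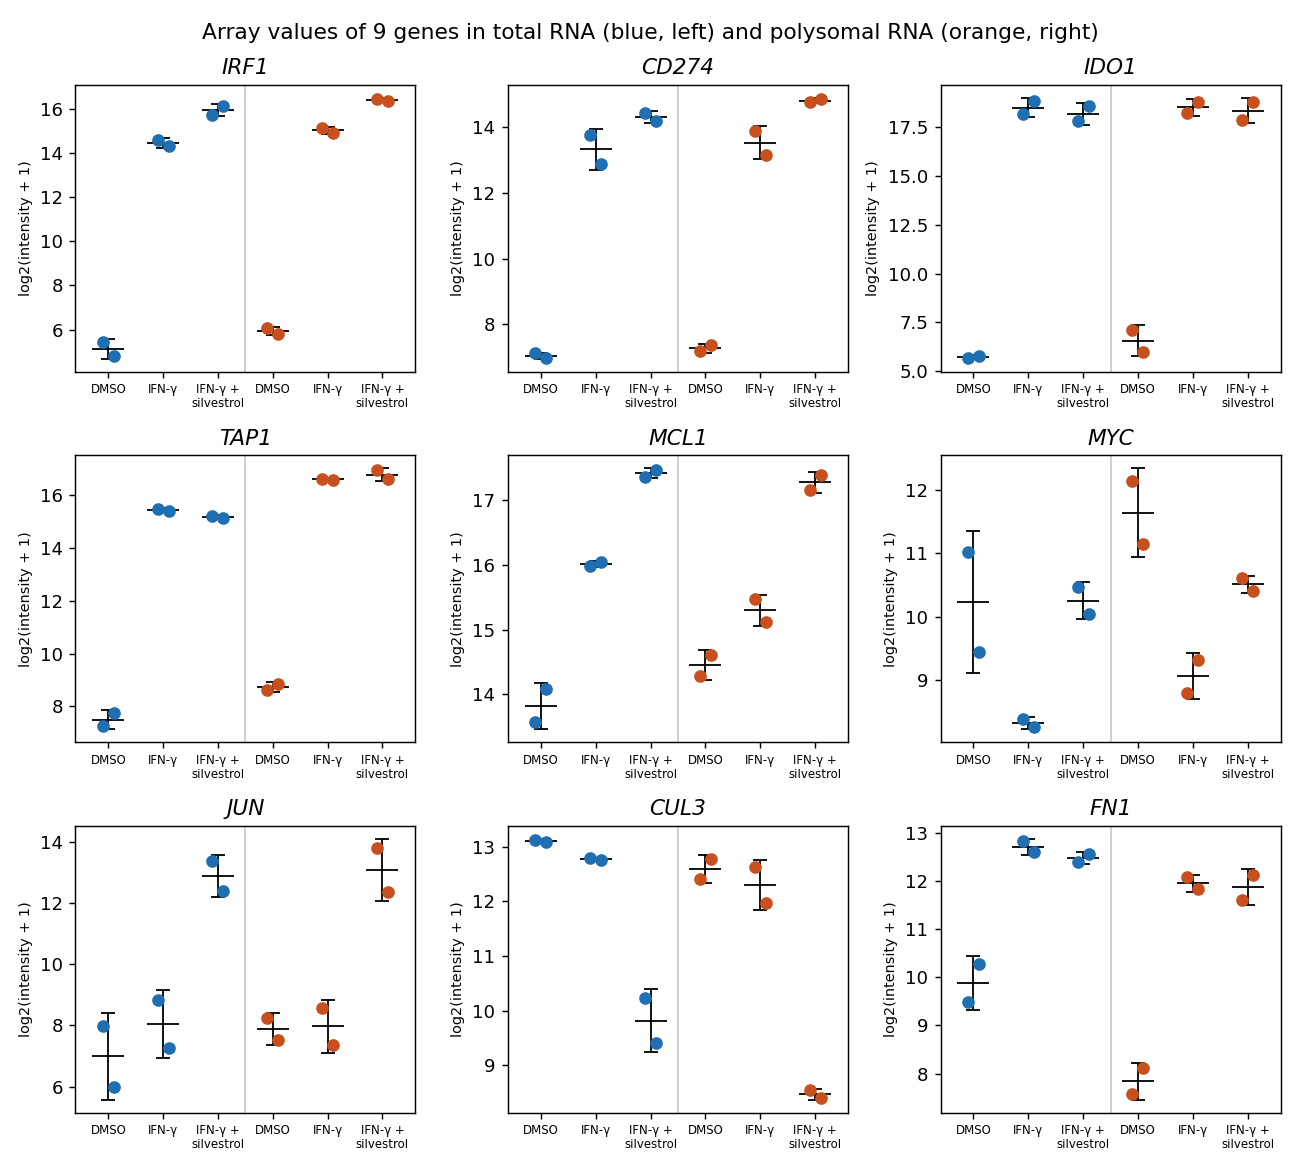
Values of each array, as log2(intensity + 1), for 9 genes in the 3 treatments, with total RNA in blue on the left of each panel and polysomal RNA in orange on the right. Points are arrays, horizontal bars are group means and error bars are SD (n = 2). IRF1, CD274, IDO1 and TAP1 rose with IFN-gamma in both fractions, JUN rose and CUL3 fell with silvestrol in both, and the mean log2 value of CD274 in total RNA was 7.05, 13.33 and 14.31 in the order of the treatments.

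Antigen presentation rose nearly as a whole. In the list of MHC class I presentation 12 of 13 measured members rose, and 12 when adjusted over the list alone (median 4.12, camera adjusted p = 2.2e-47), with HLA-F (4.90 ± 0.28), the immunoproteasome subunit PSMB9 (5.20 ± 0.36) and TAP2 (4.64 ± 0.31) among them. All 12 measured members of MHC class II presentation rose, also adjusted over the list alone (median 4.48, adjusted p = 5.0e-42), including HLA-DQA1 (6.24 ± 0.36), HLA-DQB1 (5.72 ± 0.39) and HLA-DPB1 (4.13 ± 0.30). In the list of interferon-induced GTPases and enzymes of tryptophan metabolism 6 of 10 rose, and 7 when adjusted over the list alone (median 5.91, adjusted p = 5.9e-23), GBP3 with 5.53 ± 0.28. Antiviral interferon-stimulated genes rose in 13 of 19, and in 16 when adjusted over the list alone (median 2.97, adjusted p = 4.5e-38), such as PARP14 (5.19 ± 0.24), DTX3L (3.78 ± 0.31), RSAD2 (3.52 ± 0.34) and PARP12 (3.22 ± 0.28). Of 14 chemokines and cytokines 6 rose, the same number when adjusted over the list alone (median 0.35, adjusted p = 1.8e-10), among them the macrophage growth factor CSF1 (4.47 ± 0.28), CXCL9 (3.44 ± 0.38) and IL15 (2.37 ± 0.23). Checkpoint ligands and receptors rose in 6 of 11, and in 6 when adjusted over the list alone (median 2.00, adjusted p = 1.1e-15), with CD274, PDCD1LG2, HLA-E (4.74 ± 0.34) and HLA-G (2.70 ± 0.26). JAK-STAT and IRF signalling, with 5 measured members, rose in 2, IRF1 and IRF2 (1.63 ± 0.28), and in 3 when adjusted over the list alone (median 1.09, adjusted p = 2.0e-06). Complement and coagulation rose in 2 of 7, C4A and C4B, which had identical values (1.72 ± 0.28), and in 4 when adjusted over the list alone (median 1.23, adjusted p = 4.1e-06). These 8 lists also passed with an estimated correlation, at adjusted p-values from 0.0032 for MHC class I to 0.035 for complement.

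The other lists that passed at the preset correlation had at most 1 member called over all genes, and none passed with an estimated correlation. Mitochondrial ribosome and oxidative phosphorylation genes were lower as a list (median -0.56, adjusted p = 3.1e-06) with 0 of 26 called and 1 adjusted over the list alone, and the adjusted p = 0.227 with an estimated correlation. Other mRNAs with a 5' terminal oligopyrimidine tract (TOP mRNAs) were lower (median -0.70, adjusted p = 0.0031) with 0 of 7 called and 4 lower adjusted over the list alone, and the adjusted p = 0.213 with an estimated correlation. Cytosolic ribosomal proteins had a median of -0.26 with 0 of 26 called in either way (adjusted p = 0.01, and adjusted p = 0.522 with an estimated correlation). The integrated stress response had a median of -0.61 and 1 of 12 called, the cystine transporter SLC7A11 (-1.48 ± 0.30), also adjusted over the list alone (adjusted p = 0.035, and adjusted p = 0.412 with an estimated correlation). Extracellular matrix and adhesion genes (median 0.32) had 1 of 15 called, fibronectin, FN1, which rose by 2.83 ± 0.31, also adjusted over the list alone (adjusted p = 0.02, and adjusted p = 0.442 with an estimated correlation). Immediate early genes (median 0.36) had 1 of 23 called, EGR1 (2.12 ± 0.44), and 1 higher and 1 lower adjusted over the list alone (adjusted p = 0.014, and adjusted p = 0.442 with an estimated correlation). The mesenchymal-like melanoma list (median 0.71) had 0 of 8 called and 1 adjusted over the list alone (adjusted p = 0.033, and adjusted p = 0.227 with an estimated correlation). Nuclear and other non-coding RNAs (median 0.32) had 1 of 10 called, also adjusted over the list alone, the RNase MRP component RMRP at 3.09 ± 0.49 (adjusted p = 0.033, and adjusted p = 0.442 with an estimated correlation). Without total IFN-gamma replicate 1 the calls of ribosomal proteins (adjusted p = 0.745), non-coding RNAs (0.358), immediate early genes (0.181), extracellular matrix (0.17), the stress response (0.117) and the mesenchymal-like list (0.114) ended. Leaving out total DMSO replicate 1 ended those of ribosomal proteins (0.901), the stress response (0.798), extracellular matrix (0.724, median -0.19) and the mesenchymal-like list (0.162). Leaving out total DMSO replicate 2 ended those of immediate early genes (0.466) and non-coding RNAs (0.267), and leaving out total IFN-gamma replicate 2 that of the mesenchymal-like list (0.058).

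NF-kB targets (median 0.04, adjusted p = 0.095) did not pass as a list, although PTGS2 rose by 1.88 ± 0.32. The remaining tested lists did not pass: initiation factors (adjusted p = 0.075), mRNAs reported to be sensitive to eIF4A (0.931), heat shock (0.588), p53 targets (0.157), cell cycle (0.054), histones (0.588), cholesterol synthesis (0.631), short-lived regulators (0.64) and the melanocyte lineage (0.222). Leukocyte markers did not change (6 measured, median 0.10, adjusted p = 0.548), and epithelial (4 measured, median 0.14) and endothelial markers (3 measured, median -0.26) were too few to test, with 0 called. None of the 15 mitochondrially encoded transcripts was measured. The number of called genes was 103 without total IFN-gamma replicate 2, against 184 with all arrays.

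The same treatment was next read in polysomal RNA. IFN-gamma raised the same kind of genes on polysomes: IDO1 by 11.96 ± 0.44, GBP1 by 9.35 ± 0.29, IRF1 by 9.10 ± 0.27, CXCL10 by 8.29 ± 0.54 and TAP1 by 7.88 ± 0.25, with adjusted p-values from 4.1e-09 to 3.9e-06. CD274 rose by 6.26 ± 0.32 (adjusted p = 4.7e-07), or 76.5-fold, from a mean intensity of 154.4 ± 14.9 to 12240 ± 4274 (SD, n = 2 each). Alongside, mRNAs of ribosomal proteins, histones and the respiratory chain were lower as lists on the polysomal IFN-gamma arrays, the arrays with the lower 99th percentile (adjusted p = 0.122, 0.203 and 0.103 with an estimated correlation). Of all genes, 260 rose and 1415 fell. Quantile normalization over all arrays shifted the median of all genes by 0.12 on the log2 scale and gave 411 higher and 532 lower of 943, and normalization within each fraction gave 405 and 529 of 934.

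Other large rises were those of CTSS (7.96 ± 0.40), GBP2 (6.95 ± 0.28), HLA-DQA1 (6.81 ± 0.36) and PARP14 (6.52 ± 0.24). PDCD1LG2 rose by 2.38 ± 0.35 (adjusted p = 0.0016) and JAK2 by 1.16 ± 0.31 (adjusted p = 0.031). The largest falls were in the G protein subunit GNG12 (-3.59 ± 0.29, adjusted p = 3.6e-05), TPD52L1 (-3.59 ± 0.30, adjusted p = 3.6e-05), the G protein regulator RGS20 (-3.28 ± 0.43) and TBC1D7 (-3.25 ± 0.40). Histone genes H1-4 (-3.25 ± 0.41), H2BC17 (-3.23 ± 0.63) and H2BC26 (-3.51 ± 0.95) and the phosphatase ACP1 (-3.20 ± 0.53) were also among them, with H2BC26 at adjusted p = 0.034. MYC fell by 2.59 on the log2 scale (SE 0.46, adjusted p = 0.0046), EIF4E by 1.94 (SE 0.38, adjusted p = 0.007) and MITF by 1.80 (SE 0.35, adjusted p = 0.0067). After quantile normalization over all arrays MITF was at -1.37 (adjusted p = 0.056, range over its 23 alternatives 0.0044 to 0.057). MCL1 was at 0.85 ± 0.26 (adjusted p = 0.054) and passed after quantile normalization over all arrays at 1.16 (adjusted p = 0.022, range over its alternatives 0.018 to 0.252). JAK1 (0.23 ± 0.33), IFNGR1 (0.07 ± 0.36) and EIF4G1 (-0.10 ± 0.41) did not pass.

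Most of the interferon lists that rose in total RNA also rose on polysomes. MHC class I rose in 12 of 13, and in 13 when adjusted over the list alone (median 3.57, adjusted p = 3.0e-30), as with TAP2 (4.74 ± 0.31), PSMB9 (4.40 ± 0.36) and HLA-F (4.34 ± 0.28). MHC class II rose in 11 of 12, and in 12 when adjusted over the list alone (median 4.37, adjusted p = 1.9e-26), HLA-DQB1 with 4.81 ± 0.39. The list of GTPases and tryptophan enzymes rose in 6 of 10, and in 6 adjusted over the list alone (median 4.51, adjusted p = 6.5e-17), GBP3 with 3.02 ± 0.28. Antiviral genes rose in 14 of 19, and in 16 adjusted over the list alone (median 2.52, adjusted p = 2.1e-24), the helicase DDX60 with 4.35 ± 0.41 and DTX3L with 3.73 ± 0.31. Checkpoint genes rose in 5 of 11, and in 6 adjusted over the list alone (median 1.36, adjusted p = 2.4e-07), and JAK-STAT and IRF signalling in 2 of 5, also adjusted over the list alone (median 0.68, adjusted p = 3.5e-05). These 6 lists passed with an estimated correlation too, at adjusted p-values from 0.011 to 0.031. Complement rose in 4 of 7, and in 5 adjusted over the list alone, C2 with 2.37 ± 0.34 and CFB with 1.70 ± 0.47 (median 1.70, adjusted p = 2.4e-05, and adjusted p = 0.056 with an estimated correlation). The called members included C4A and C4B, whose identical values (1.70 ± 0.28) were counted for both. Chemokines and cytokines had 4 higher, 1 lower and, adjusted over the list alone, 5 higher and 2 lower of 14. Their median was -0.04, their mean 1.13 and the test pointed up (adjusted p = 0.0011, and adjusted p = 0.064 with an estimated correlation), and median centring turned the median to 0.05. In that list the death ligand TNFSF10 rose by 3.71 ± 0.67 and CSF1 by 3.90 ± 0.28, and CCL20 fell by 1.06 (SE 0.27).

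Extracellular matrix and adhesion had 6 of 15 higher, 7 adjusted over the list alone, with FN1 at 4.11 ± 0.31, the collagen receptor ITGA2 at 2.19 ± 0.35, the laminin chain LAMC1 at 1.90 ± 0.28 and COL5A2 at 1.12 ± 0.24. The list's median was 0.09 (adjusted p = 3.5e-05, and adjusted p = 0.179 with an estimated correlation). The mesenchymal-like list had 1 of 8 higher, also adjusted over the list alone, VGF at 1.36 ± 0.34 (median 0.18, adjusted p = 0.014, and adjusted p = 0.122 with an estimated correlation). With all clusters tested this list's camera call ended (adjusted p = 0.077).

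The genes that fell on polysomes included growth and housekeeping mRNAs. Histones fell in 24 of 41, and in 31 adjusted over the list alone (median -1.53, adjusted p = 4.1e-13, and adjusted p = 0.203 with an estimated correlation), as with H2BC5 (-2.18 ± 0.36) and H2AC12 (-1.50 ± 0.27). Cytosolic ribosomal proteins fell in 15 of 26, and in 22 adjusted over the list alone (median -1.18, adjusted p = 2.5e-12, and adjusted p = 0.122 with an estimated correlation), RPL29 at -2.64 ± 0.44, RPL22 at -2.23 ± 0.27 and RPL31 at -2.13 ± 0.25. Mitochondrial ribosome and oxidative phosphorylation genes fell in 17 of 26, and in 23 adjusted over the list alone (median -1.29, adjusted p = 3.1e-10, and adjusted p = 0.103 with an estimated correlation), cytochrome c, CYCS, at -2.16 ± 0.32 and MRPL13 at -1.85 ± 0.34. Initiation factors fell in 6 of 11, and in 7 adjusted over the list alone (median -0.98, adjusted p = 0.00061, and adjusted p = 0.079 with an estimated correlation), among them the eIF4E repressor EIF4EBP1 (-2.79 ± 0.31) and the eIF4E relative EIF4E2 (-2.77 ± 0.32). Other TOP mRNAs fell in 3 of 7, also adjusted over the list alone, with BTF3 at -1.64 ± 0.24 and NPM1 at -1.43 ± 0.25 (median -0.71, adjusted p = 0.0022, and adjusted p = 0.122 with an estimated correlation). p53 targets fell in 4 of 14, and in 8 adjusted over the list alone, ZMAT3 at -2.12 ± 0.26 and the cell cycle inhibitor CDKN1A at -1.87 ± 0.38 (median -0.88, adjusted p = 0.00065, and adjusted p = 0.122 with an estimated correlation). Short-lived regulators fell in 3 of 11, and in 7 adjusted over the list alone, CITED2 at -2.31 ± 0.52 (median -0.65, adjusted p = 0.0053, and adjusted p = 0.116 with an estimated correlation). Quantile normalization over all arrays ended that list's call (median -0.14, adjusted p = 0.141; 0.14 to 0.212 over the 3 alternatives that ended it). The melanocyte lineage fell in 2 of 5, also adjusted over the list alone, MITF and the antigen MLANA at -1.40 ± 0.36 (median -0.79, adjusted p = 0.049, and adjusted p = 0.122 with an estimated correlation). Its call ended in 9 alternatives, among them without polysomal IFN-gamma replicate 2 (adjusted p = 0.178), polysomal DMSO replicate 1 (0.057) or 2 (0.066), or total IFN-gamma replicate 1 or 2 (0.056 each).

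Lists that did not pass on polysomes were mRNAs reported to be sensitive to eIF4A (adjusted p = 0.164), with MET higher (1.14 ± 0.29) and MYC, CCND3 (-1.42 ± 0.35) and SKP2 (-1.27 ± 0.27) lower, and immediate early genes (0.126), where ID3 fell (-2.53 ± 0.54). NF-kB targets (0.753), the stress response (0.558), heat shock (0.819), cell cycle (0.434), cholesterol synthesis (0.819), non-coding RNAs (0.635) and leukocyte markers (0.339) did not pass either. In these lists the chaperonin subunit HSPE1 (-1.81 ± 0.30) and RMRP (-1.77 ± 0.49) fell. The endothelial marker KDR fell by 1.28 (SE 0.32). Without polysomal DMSO replicate 2 the comparison called 708 genes, against 1675.

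Across the 15196 genes the IFN-gamma effects in the 2 fractions correlated at a Pearson coefficient of 0.622 and a Spearman coefficient of 0.389, and genes are not independent replicates. Of the 152 genes higher in total RNA 119 were also higher in polysomal RNA, where 2.60 would be shared by chance, and 29 of the 32 lower genes were lower in both. RMRP and NREP were the 2 genes called higher in total and lower in polysomal RNA. The test of the difference between the fractions found 0 genes with limma (1466 at an unadjusted p under 0.05), while with all clusters tested 26 clusters with a symbol and 88 without passed. Its smallest adjusted p was 0.085, and the genes with the smallest p were UMAD1 (-2.41), GBP3 (-2.51 ± 0.40), NREP (-3.41) and RMRP (-4.86). CD274 had a difference of -0.02 ± 0.46 (adjusted p = 0.996), IRF1 of -0.23 ± 0.39 (adjusted p = 0.916) and MCL1 of -1.35 ± 0.36 (adjusted p = 0.255). The median SE of such a difference was 0.42.

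**Figure D2:**
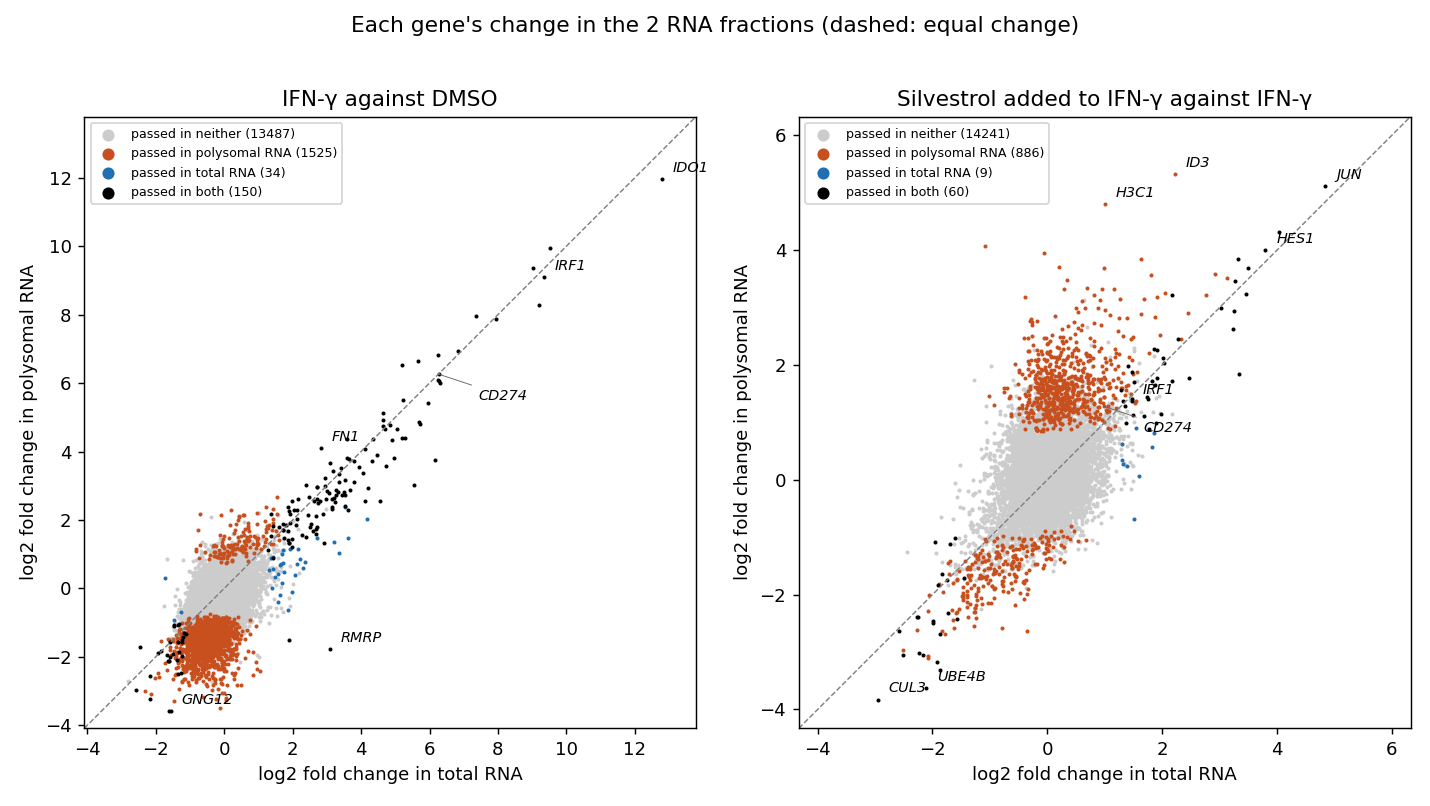
Log2 fold change of each of 15196 genes in total RNA (horizontal axis) against polysomal RNA (vertical axis), for IFN-gamma against DMSO (left) and for silvestrol with IFN-gamma against IFN-gamma (right). Points are coloured by the fractions in which the gene passed an adjusted p of 0.05, and the dashed line marks equal change. On the left the 119 genes called higher in both fractions lie at positive values of both axes, while on the right many genes passed in polysomal RNA that did not pass in total RNA, although 0 genes passed limma's test of the difference.

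Silvestrol was next examined as an addition to IFN-gamma, against IFN-gamma alone. In total RNA it raised transcription factors of the immediate early class and lowered a small group of mRNAs led by CUL3, a scaffold of ubiquitin ligases. JUN rose by 4.84 ± 0.73 (adjusted p = 0.016), the nuclear receptor NR4A2 by 4.03 ± 0.42 (adjusted p = 0.0021) and HES1, a Notch target, by 3.80 ± 0.31 (adjusted p = 0.00038). CUL3 fell by 2.95 (SE 0.31, adjusted p = 0.0021), which was 7.74-fold. In all, 47 genes rose and 22 fell.

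KLF10 (3.50 ± 0.38), the matricellular CCN1 (3.46 ± 0.57), the SMAD co-repressor SKIL (3.35 ± 0.36), CSRNP1 (3.33 ± 0.41) and EGR3 (3.27 ± 0.50) completed the largest rises, with adjusted p-values from 0.0026 to 0.024. After CUL3 the largest falls were in PCYOX1 (-2.59 ± 0.35), SV2A (-2.51 ± 0.31), the prolyl hydroxylase P3H2 (-2.28 ± 0.28) and the lipoprotein receptor VLDLR (-2.25 ± 0.32). CLCN3 (-2.23 ± 0.34), ADAM23 (-2.17 ± 0.33) and the ubiquitin ligase UBE4B (-2.11 ± 0.28) followed, with adjusted p-values of the falls from 0.0021 to 0.016. IRF1 rose by 1.48 ± 0.27 (adjusted p = 0.042) and MCL1 by 1.40 ± 0.26 (adjusted p = 0.039). The IRF1 call ended in 12 of its 23 alternatives (adjusted p from 0.022 to 0.336), among them without total IFN-gamma replicate 1 (0.15) or 2 (0.244) or total IFN-gamma plus silvestrol replicate 1 (0.212) or 2 (0.336). Leaving out the same 4 arrays in that order gave MCL1 adjusted p-values of 0.214, 0.178, 0.315 and 0.254, in a range from 0.02 to 0.315 over its 23 alternatives. CD274 was at 0.98 ± 0.32 (adjusted p = 0.345) and MYC at 1.94 ± 0.46 (adjusted p = 0.13). Neither IDO1 (-0.31 ± 0.44), GBP1 (-0.07 ± 0.29), TAP1 (-0.26 ± 0.25), CXCL10 (0.67 ± 0.54) nor PDCD1LG2 (-0.58 ± 0.35) passed. JAK1 (-0.70 ± 0.33), JAK2 (0.44 ± 0.31), IFNGR1 (0.22 ± 0.36), EIF4E (0.17 ± 0.38), EIF4G1 (-0.81 ± 0.41) and MITF (0.50 ± 0.35) did not pass.

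Immediate early genes rose as a list: 7 of 23 passed over all genes and 20 when adjusted over the list alone (median 1.94, adjusted p = 1.3e-36, and adjusted p = 0.045 with an estimated correlation), with ATF3 at 3.25 ± 0.54. Short-lived regulators had 3 of 11 higher and 1 lower, and 5 higher and 1 lower adjusted over the list alone (median 0.92, adjusted p = 3.7e-06, and adjusted p = 0.071 with an estimated correlation). Their higher members were the circadian repressor BHLHE40 (3.23 ± 0.23), KBTBD2 (1.82 ± 0.29) and ZBTB2 (1.47 ± 0.28), and the lower one was CUL3. NF-kB targets rose in 2 of 16, PTGS2 (2.27 ± 0.32) and IRF1, and in 6 adjusted over the list alone (median 0.39, adjusted p = 4.8e-06, and adjusted p = 0.218 with an estimated correlation). Histones were higher as a list (median 0.69, adjusted p = 3.7e-09, and adjusted p = 0.587 with an estimated correlation) with 0 of 41 called in either way. The mesenchymal-like list had 2 of 8 higher, JUN and CCN1, and 3 adjusted over the list alone (median 0.09, adjusted p = 0.033, and adjusted p = 0.389 with an estimated correlation). Complement was lower as a list with 0 of 7 called in either way (median -0.45, adjusted p = 0.033, and adjusted p = 0.457 with an estimated correlation). Its members C4A and C4B had identical values (-0.45 ± 0.28), so the same measurement was counted for both. The last 2 calls ended without total IFN-gamma replicate 1 (adjusted p = 0.118 and 0.265) and without total IFN-gamma plus silvestrol replicate 1 (0.265 and 0.121).

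Antigen presentation did not change detectably: MHC class I had a median of -0.19 (adjusted p = 0.113), MHC class II of -0.11 (0.291), the list of GTPases and tryptophan enzymes of -0.12 (0.806), antiviral genes of 0.14 (0.439) and checkpoint genes of -0.51 (0.057), each with 0 called. mRNAs reported to be sensitive to eIF4A had 1 of 9 higher, MCL1, and 2 higher and 1 lower adjusted over the list alone (median 0.22, adjusted p = 0.439). Ribosomal proteins (0.291), oxidative phosphorylation (0.806), other TOP mRNAs (0.16), initiation factors (0.806), JAK-STAT signalling (0.262), chemokines (0.467), the stress response (0.118) and heat shock (0.519) did not pass. Nor did p53 targets (0.262), cell cycle (0.978), cholesterol synthesis (0.806), extracellular matrix (0.118), the melanocyte lineage (0.213), non-coding RNAs (0.203) or leukocyte markers (0.806). Single arrays weighed heavily here: without total IFN-gamma plus silvestrol replicate 1 the count was 4, against 69. Of the 23 called genes named by the rule 3 passed in all 23 alternatives: HES1, BHLHE40 and CUL3.

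On polysomes silvestrol raised immediate early genes and histone mRNAs as lists, against the polysomal IFN-gamma arrays, and lowered CUL3 and UBE4B. With an estimated correlation the 2 lists did not pass (adjusted p = 0.196 and 0.284). ID3, an inhibitor of helix-loop-helix factors, rose by 5.33 ± 0.54 (adjusted p = 0.00077), JUN by 5.12 ± 0.73 (adjusted p = 0.0032) and the histone H3C1 by 4.80 ± 0.67 (adjusted p = 0.0029). CUL3 fell by 3.83 (SE 0.31, adjusted p = 0.00022), which was 14.2-fold, and UBE4B by 3.62 (SE 0.28, adjusted p = 0.00022), which was 12.3-fold. The comparison found 687 higher and 259 lower genes. Median centring shifted the median of all genes by -0.11 and gave 559 higher and 343 lower, and quantile normalization over all arrays gave 533 and 421 of 954, while within each fraction it gave 530 and 428.

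NR4A2 (4.31 ± 0.42), RMRP (4.07 ± 0.49), HES1 (4.0 ± 0.31), H2BC17 (3.84 ± 0.63) and CSRNP1 (3.84 ± 0.41) completed the largest rises, with adjusted p-values from 0.00022 to 0.0057. The falls continued with ABCE1, an ATPase of ribosome recycling (-3.31 ± 0.33), FASTKD1 (-3.17 ± 0.36), the guidance receptor ROBO1 (-3.10 ± 0.47), TMEM184C (-3.07 ± 0.59), SV2A (-3.06 ± 0.31) and ADAM23 (-3.05 ± 0.33), with adjusted p-values from 0.00077 to 0.011. Outside the largest changes, MCL1 rose by 1.98 ± 0.26 (adjusted p = 0.0022), IRF1 by 1.37 ± 0.27 (adjusted p = 0.013) and CD274 by 1.28 ± 0.32 (adjusted p = 0.038). CD274 mean intensity was 12240 ± 4274 with IFN-gamma and 28840 ± 1549 with silvestrol added (SD, n = 2 each). The CD274 call ended in 11 of its 23 alternatives, among them quantile normalization over all arrays (1.02, adjusted p = 0.114) and leaving out polysomal IFN-gamma replicate 2 (0.92, adjusted p = 0.257) or polysomal IFN-gamma plus silvestrol replicate 1 (1.34, 0.157) or 2 (1.23, 0.127), over a range from 0.022 to 0.257. JAK1 fell by 1.26 (SE 0.33, adjusted p = 0.042). MYC (1.45 ± 0.46, adjusted p = 0.092), CXCL10 (1.30 ± 0.54, adjusted p = 0.202) and GBP1 (-0.71 ± 0.29, adjusted p = 0.202) did not pass. IDO1 (-0.17 ± 0.44), TAP1 (0.18 ± 0.25), PDCD1LG2 (-0.18 ± 0.35), JAK2 (-0.32 ± 0.31), IFNGR1 (0.49 ± 0.36), EIF4E (0.85 ± 0.38), EIF4G1 (-0.48 ± 0.41) and MITF (0.39 ± 0.35) did not pass either.

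Histones rose in 30 of 41 and, adjusted over the list alone, in 39 (median 2.39, adjusted p = 4.3e-29, and adjusted p = 0.284 with an estimated correlation), H1-4 with 3.34 ± 0.41 and H2BC7 with 3.22 ± 0.41. Immediate early genes rose in 15 of 23 and, adjusted over the list alone, in 22 (median 2.91, adjusted p = 1.9e-20, and adjusted p = 0.196 with an estimated correlation). Cytosolic ribosomal proteins rose in 9 of 26 and, adjusted over the list alone, in 20 (median 1.13, adjusted p = 6.8e-10, and adjusted p = 0.4 with an estimated correlation), RPL31 with 1.85 ± 0.25 and RPS27 with 1.60 ± 0.28. Mitochondrial ribosome and oxidative phosphorylation genes rose in 8 of 26 and, adjusted over the list alone, in 17 (median 1.03, adjusted p = 2.2e-08, and adjusted p = 0.284 with an estimated correlation), NDUFA2 with 2.25 ± 0.44 and MRPL20 with 1.62 ± 0.33. These 4 medians are measured against the polysomal IFN-gamma arrays, where 3 of the lists were lower than in DMSO cells. Non-coding RNAs rose in 4 of 10 and, adjusted over the list alone, in 7 (median 1.52, adjusted p = 3.3e-05, and adjusted p = 0.284 with an estimated correlation), with the splicing RNA RNU11 at 3.57 ± 0.43. Short-lived regulators had 4 of 11 higher and 1 lower, and 8 higher and 2 lower adjusted over the list alone (median 1.09, adjusted p = 0.012, and adjusted p = 0.284 with an estimated correlation), BHLHE40 with 2.64 ± 0.23. NF-kB targets rose in 4 of 16 and, adjusted over the list alone, in 5, among them TNFAIP3 (2.52 ± 0.40), PTGS2 (2.45 ± 0.32) and NFKBIE (1.87 ± 0.30), with a median of 0.25 (adjusted p = 0.015, and adjusted p = 0.512 with an estimated correlation). The list of GTPases and tryptophan enzymes was lower with 2 of 10 called, also adjusted over the list alone, the GTPase GBP2 (-1.20 ± 0.28) and the kynurenine enzyme KYNU (-1.38 ± 0.27), and a median of -0.46 (adjusted p = 0.021, and adjusted p = 0.551 with an estimated correlation). Extracellular matrix genes were lower with 1 of 15 called, also adjusted over the list alone, ITGAV (-1.53 ± 0.41), and a median of -0.20 (adjusted p = 0.015, and adjusted p = 0.551 with an estimated correlation). Without polysomal IFN-gamma plus silvestrol replicate 1 the calls of NF-kB targets and of GTPases and tryptophan enzymes ended (adjusted p = 0.1 and 0.678, with the second median at 0.11), and without polysomal IFN-gamma replicate 2 that of NF-kB targets ended (adjusted p = 0.06).

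Antigen presentation did not change detectably on polysomes either, with MHC class I at a median of 0.21 (adjusted p = 0.927, -0.08 after quantile normalization over all arrays) and MHC class II at -0.08 (adjusted p = 0.579). Antiviral genes (0.458) had ISG15 higher (2.01 ± 0.36) and PARP14 lower (-0.89 ± 0.24, adjusted p = 0.0498), and checkpoint genes (0.88) had CD274 higher. mRNAs reported to be sensitive to eIF4A did not pass (median 0.44, adjusted p = 0.567). MCL1 was higher there and MET (-1.16 ± 0.29) and SKP2 (-1.07 ± 0.27) were lower, and 3 were higher and 2 lower adjusted over the list alone. The mesenchymal-like list (0.132) had 3 of 8 higher, CCN2 with 3.52 ± 0.72, and p53 targets (0.326) had CDKN1A higher (3.18 ± 0.38). Initiation factors (0.579) had EIF4EBP1 higher (2.21 ± 0.31), cholesterol synthesis (0.801) had PMVK higher (1.66 ± 0.43) and squalene epoxidase, SQLE, lower (-2.31 ± 0.49), and the stress response (0.326) had SLC7A11 lower (-2.30 ± 0.30). JAK-STAT signalling (0.821), chemokines (0.775), complement (0.579), other TOP mRNAs (0.132), heat shock (0.129), cell cycle (0.801), the melanocyte lineage (0.354) and leukocyte markers (0.579) did not pass. Without polysomal IFN-gamma plus silvestrol replicate 1 the count fell to 157, against 946, and 30 of the 60 called genes named by the rule passed in all 23 alternatives.

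**Figure D3:**
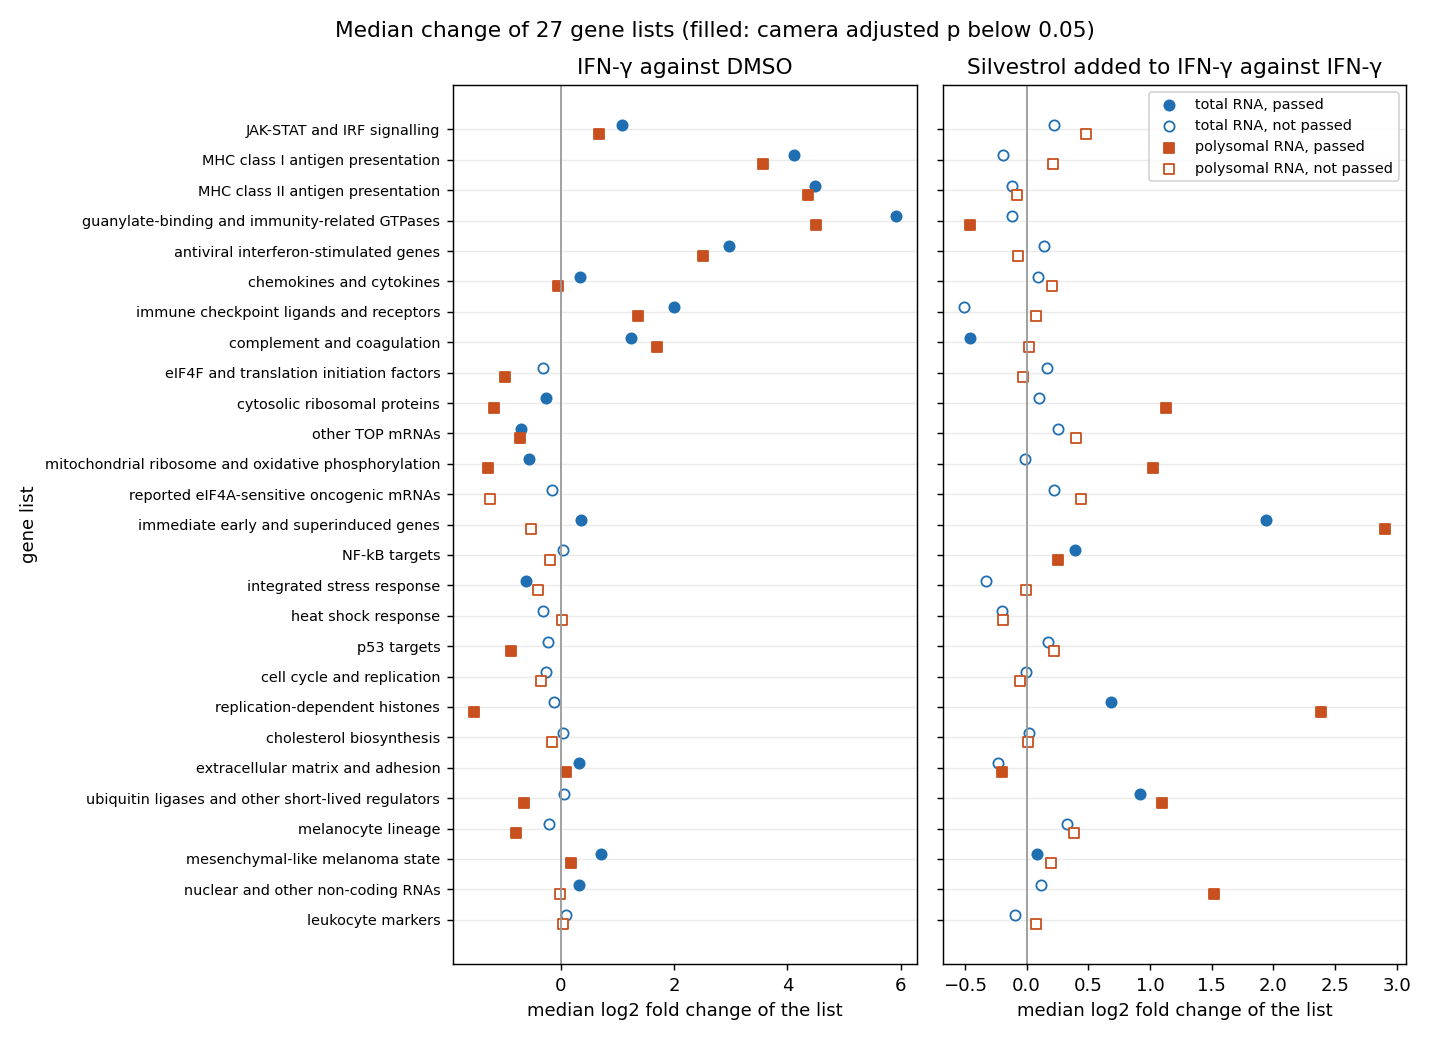
Median log2 fold change of 27 gene lists for IFN-gamma against DMSO (left) and for silvestrol with IFN-gamma against IFN-gamma (right), in total RNA (blue circles) and polysomal RNA (orange squares). Filled symbols passed camera at an adjusted p of 0.05 with the preset correlation. The MHC class I, MHC class II, antiviral and checkpoint lists stand at positive values on the left in both fractions. Histones stand at -1.53 on the left and 2.39 on the right in polysomal RNA.

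Whether silvestrol changed polysome loading beyond the change in total RNA was tested as the difference of its effects between the fractions. Values were taken as scaled between arrays, so a general change in polysome loading could not be seen, only changes relative to other genes. With 1 cluster per gene limma found 0 genes, with 1333 at an unadjusted p under 0.05, while with all clusters tested 1 cluster with a symbol and 11 without passed. RMRP came closest (5.16 ± 0.69, adjusted p = 0.128), followed by PRRT3-AS1 (2.35), PSMB8-AS1 (1.98) and FBXO30 (-2.20), each at adjusted p = 0.172. The IFN-gamma difference of RMRP had the opposite sign (-4.86 ± 0.69). Both differences use the same IFN-gamma arrays, so the value for silvestrol is not a separate finding. CD274 differed by 0.30 ± 0.46 (adjusted p = 0.924), IRF1 by -0.11 ± 0.39 (adjusted p = 0.972), MCL1 by 0.58 ± 0.36 (adjusted p = 0.721), MYC by -0.49 (adjusted p = 0.908) and JAK1 by -0.57. Histones (median 1.77, adjusted p = 4.5e-19), ribosomal proteins (1.03, adjusted p = 1.8e-08), oxidative phosphorylation (0.98, adjusted p = 1.9e-08) and non-coding RNAs (1.17, adjusted p = 0.0007) were higher as lists in this difference, each at adjusted p = 0.728 with an estimated correlation. The reference here includes the polysomal IFN-gamma arrays, which stood apart, and for IFN-gamma the difference of histones, ribosomal proteins and oxidative phosphorylation had the opposite sign (-1.40, -0.85 and -0.74). Against DMSO cells the pooled difference between fractions of these 3 lists with silvestrol was 0.12. Adjusted over the list alone, 20 of 41 histones, 11 of 26 ribosomal proteins, 1 of 26 oxidative phosphorylation genes and 4 of 10 non-coding RNAs were higher. Immediate early genes (median 0.20, adjusted p = 0.503) and mRNAs reported to be sensitive to eIF4A (-0.01, adjusted p = 0.931) did not differ detectably.

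Silvestrol effects in the fractions correlated at a Pearson coefficient of 0.452 and a Spearman coefficient of 0.266 across genes. Of the 47 genes higher in total RNA 38 were also higher on polysomes, where 2.12 would be shared by chance, and all 22 lower genes were lower on polysomes. None of them was called in opposite directions.

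Genes induced by IFN-gamma in 1 fraction were then followed under silvestrol in the other, so that no array entered both choices. The 260 genes induced on polysomes had a median silvestrol effect of -0.12 in total RNA (quartiles -0.47 and 0.17), with 155 of them negative. The median was -0.27 without polysomal DMSO replicate 2 and -0.09 without total IFN-gamma plus silvestrol replicate 1. Over all genes 0 of them were called lower and 4 higher, and 8 lower and 8 higher when adjusted over the list alone. Camera placed them below other genes (adjusted p = 0.014 over these 2 lists, and adjusted p = 0.387 with an estimated correlation). The 152 genes induced in total RNA had a median of 0.05 on polysomes, with 10 lower and 13 higher, and 12 lower and 19 higher adjusted over the list alone (adjusted p = 0.744). With all clusters tested, the median of the genes induced in total RNA was 0.27 on polysomes, and after quantile normalization over all arrays it was -0.14. With 1 array left out it ran from -0.07 (without total DMSO replicate 2) to 0.18 (without total DMSO replicate 1). It was also negative without either total IFN-gamma array (-0.07 and -0.06) or either polysomal DMSO array (-0.02 each), and it was 0.16 without polysomal IFN-gamma replicate 2 and 0.14 without polysomal IFN-gamma plus silvestrol replicate 1.

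Polysomal and total RNA of DMSO cells were compared to show how the fractions differ without treatment. Members of the MHC class I list were among the genes higher on polysomes: HLA-C was higher by 1.93, HLA-E by 1.82 and the peptide-loading factor TAPBP by 1.86. PRKDC, which encodes the catalytic subunit of the DNA-dependent protein kinase, was lower (-3.77 ± 0.24, adjusted p = 4.3e-05). In all, 149 genes were higher and 55 lower on polysomes, while quantile normalization over all arrays gave 42 higher and 56 lower, and within each fraction 49 and 90.

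The largest positive differences were in the histone H3C10 (2.56), the pyroptosis effector GSDMD (2.25), THAP4 (2.24), the riboflavin transporter SLC52A2 (2.22), HGH1 (2.21), ADAM15 (2.19), the importin IPO13 (2.14) and ACY1 (2.14), with adjusted p-values up to 0.049. The largest negative ones were in PRKDC, EPRS1 (-2.91), MDN1 (-2.67), SCARNA7 (-2.65), BIRC6 (-2.37), the minor splicing RNA RNU4ATAC (-2.31), PRRC2C (-2.24) and LRPPRC (-2.15). FN1 (-2.03 ± 0.31) and PARP14 (-2.11) were also lower. MHC class I was higher in 6 of 13, and 10 higher and 1 lower adjusted over the list alone (median 1.38, adjusted p = 7.1e-08, and adjusted p = 0.349 with an estimated correlation). MHC class II had 0 of 12 called and 2 adjusted over the list alone (median 0.94, adjusted p = 0.0035, and adjusted p = 0.523 with an estimated correlation). Histones had 1 of 41 higher and 4 adjusted over the list alone (median 0.80, adjusted p = 1.5e-09), immediate early genes 1 of 23 and 5 adjusted over the list alone (0.65, adjusted p = 0.00051) and p53 targets 0 of 14 and 3 adjusted over the list alone (0.62, adjusted p = 0.013), each at adjusted p = 0.489 with an estimated correlation. Oxidative phosphorylation had 1 of 26 higher, MRPL24 (1.59), and 4 adjusted over the list alone (median 0.38, adjusted p = 0.0025, and adjusted p = 0.513 with an estimated correlation). Non-coding RNAs were lower with 1 of 10 called and 4 adjusted over the list alone (median -0.95, adjusted p = 1.6e-06, and adjusted p = 0.42 with an estimated correlation). Extracellular matrix genes were lower with 2 of 15 called, FN1 and ITGA2 (-1.81), and 6 lower and 1 higher adjusted over the list alone (median -0.40, adjusted p = 0.00051, and adjusted p = 0.489 with an estimated correlation). With the replicate number as a block the comparison called 328 genes, 245 higher and 83 lower, against 204.

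Single arrays weighed on most of these list values. Without total DMSO replicate 2 the calls ended for histones (median 0.26, adjusted p = 0.286), p53 targets (0.37, adjusted p = 0.362), oxidative phosphorylation (0.14, adjusted p = 0.316), extracellular matrix (-0.20, adjusted p = 0.297) and immediate early genes (0.57, adjusted p = 0.077). Without polysomal DMSO replicate 2 MHC class II was at 0.12 (adjusted p = 0.565) and oxidative phosphorylation at -0.01 (adjusted p = 0.388). MHC class II was at 0.27 (adjusted p = 0.609) without total DMSO replicate 1, and p53 targets were at 0.28 (adjusted p = 0.107) without polysomal DMSO replicate 1. Without polysomal DMSO replicate 2 the comparison called 1 gene, and of 28 called genes named by the rule PRKDC alone passed in all 23 alternatives.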

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

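The comparisons of IFN-gamma plus silvestrol with DMSO and the readings of the polysomal effects of CD274 and IRF1 were tests chosen only after the result was seen.

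Histone, ribosomal protein and oxidative phosphorylation mRNAs were lower with IFN-gamma on polysomes (pooled median -1.31 over 93 members) than in total RNA (-0.25), a difference of -0.997 between the fractions. A compressed signal scale of the polysomal IFN-gamma arrays was argued against as the whole cause by the difference of -0.6712 left after quantile normalization. Equal loss of signal by all genes of this brightness was argued against by random lists matched on level, with a median of -0.2441. The percentile was 0 among 10000 such lists, whose lowest median was -0.603. That percentile is no independent p-value. The 3 lists had already passed camera in this same difference, and random genes need not vary together as list members do. A single deviating polysomal IFN-gamma array was argued against by the -0.7646 left without replicate 1 (-1.22 without replicate 2). For IFN-gamma plus silvestrol against DMSO the difference was 0.1234. This comparison cannot decide whether the IFN-gamma effect persisted, since no cells were given silvestrol alone. A rise caused by silvestrol itself could offset an effect that persisted. The collection and quality of the polysomal IFN-gamma fractions, which coincide with the group, stay open. So do an IFN-gamma effect undone by silvestrol and one that persisted beneath such a rise. With an estimated correlation the 3 lists did not pass in this difference (adjusted p = 0.468).

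IRF1 was higher with silvestrol in both fractions, and CD274 was higher on polysomes and did not pass in total RNA (0.98, adjusted p = 0.345). For IRF1, chance low values of the total IFN-gamma arrays were argued against as the whole cause by its rise of 1.3676 ± 0.273 (SE) on polysomes, which rests on other arrays. Both fractions may come from the same cultures, so low values shared by the IFN-gamma cultures are not covered. For CD274 the rise of 1.281 ± 0.323 on polysomes uses none of the total arrays either, but it is the call that brought the gene into the pattern, so it is no separate test. A common rise of IFN-gamma-induced mRNAs was argued against in total RNA by the median of -0.1234 of genes induced on polysomes. On polysomes, where CD274 passed, genes induced in total RNA had a median of 0.05, with 13 called higher and 10 lower. That median ran from -0.07 to 0.18 with 1 array left out, so the argument is made for total RNA alone. Slower decay of short-lived mRNAs under blocked translation was not tested and stays open. The CD274 call on polysomes ended in 11 of 23 alternatives (adjusted p from 0.022 to 0.257), and the IRF1 call ended in 12 of 23 in total RNA (0.022 to 0.336) and in 2 of 23 on polysomes (0.0096 to 0.108), without polysomal IFN-gamma replicate 2 (0.099) or polysomal IFN-gamma plus silvestrol replicate 1 (0.108).

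The test of the difference between the fractions singled out 13 list results. The silvestrol and IFN-gamma differences share the 4 IFN-gamma arrays with opposite sign, and 3 of the 4 silvestrol results, those of histones, ribosomal proteins and oxidative phosphorylation, mirror IFN-gamma results, so they are not separate findings. The silvestrol result of non-coding RNAs rests on the same arrays. Its member RMRP, which came closest under silvestrol, had an IFN-gamma difference of -4.86. For the silvestrol effect the cytosolic ribosomal proteins differed by a median of 1.028 (camera adjusted p = 1.8e-08), oxidative phosphorylation by 0.9767 (1.9e-08), histones by 1.7718 (4.5e-19) and non-coding RNAs by 1.1678 (0.0007). For the IFN-gamma effect the lower values on polysomes were those of histones (-1.398, adjusted p = 1.3e-13), ribosomal proteins (-0.8539, 2.1e-09), short-lived regulators (-0.7629, 0.02), oxidative phosphorylation (-0.7415, 0.0005) and immediate early genes (-0.6749, 0.00067). Chemokines (-0.6159, 0.011), p53 targets (-0.4747, 0.018) and initiation factors (-0.357, 0.011) were lower too, while extracellular matrix genes were higher (0.3617, 0.0015). With an estimated correlation none of these passed, with adjusted p-values of 0.728 for silvestrol and 0.415 to 0.468 for IFN-gamma. Quantile normalization over all arrays ended the IFN-gamma calls of initiation factors (-0.04, adjusted p = 0.094), p53 targets (-0.19, 0.184), short-lived regulators (-0.34, 0.195) and oxidative phosphorylation (-0.39, 0.0503).

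Single arrays also ended IFN-gamma calls in this difference. Without total DMSO replicate 2 they were those of extracellular matrix genes (0.12, adjusted p = 0.334), p53 targets (-0.16, 0.312) and short-lived regulators (-0.38, 0.137), and without total DMSO replicate 1 that of chemokines (-0.66, 0.054). Without polysomal DMSO replicate 1 they were those of initiation factors (-0.51, 0.104), p53 targets (-0.47, 0.112) and short-lived regulators (-0.47, 0.112), and without replicate 2 that of chemokines (-0.45, 0.062). Without total IFN-gamma replicate 1 chemokines (-0.56, 0.074), p53 targets (-0.52, 0.146) and short-lived regulators (-0.83, 0.074) did not pass, and without polysomal IFN-gamma replicate 2 short-lived regulators did not (-0.69, 0.079).

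A signal also appeared among the 48986 clusters without a gene symbol, which the comparisons of genes do not use. With all clusters tested, IFN-gamma changed 57 of them in total RNA (50 higher, 7 lower) and 454 on polysomes (132 higher, 322 lower). Silvestrol changed 5 in total RNA (5 higher, 0 lower by limma) and 316 on polysomes (254 higher, 62 lower). In the differences between fractions 88 of them passed for IFN-gamma (5 higher, 83 lower) beside 26 clusters with a symbol, and 11 for silvestrol (11 higher) beside 1 with a symbol.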

How the results depend on the processing

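The use of the IFN-gamma plus silvestrol arrays in place of the IFN-gamma arrays was a test chosen only after the result was seen, and gave 1300 genes on polysomes (446 higher, 854 lower). Values below are numbers of genes called unless stated otherwise, and the cause was not tested where none is given.

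Quantile normalization over all arrays gave 943 for IFN-gamma on polysomes and 98 for polysomal against total RNA in DMSO cells, and within each fraction 934 for IFN-gamma on polysomes. With only the arrays of the contrast, and so fewer arrays to estimate the spread, IFN-gamma in total RNA gave 108, silvestrol in total RNA 27, the IFN-gamma difference between fractions 1 and the DMSO comparison 1. An intensity trend with robust spread gave 1 for each difference between fractions and 68 in DMSO cells. Array quality weights gave 111 for silvestrol in total RNA and 76 in DMSO cells. These weights were equal for the 2 arrays of each group, so they weighed groups and could not single out an array. A pseudocount of 16 gave 1 for the IFN-gamma difference and 131 in DMSO cells. Among genes at or above the median level the silvestrol difference gave 1, the IFN-gamma difference 2 and the correlation of silvestrol effects between fractions 0.5368, and at or above the 25th percentile the silvestrol difference gave 1 and the correlation 0.4808, with fewer genes tested. The cause was not tested for the others.

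With all clusters tested, silvestrol in total RNA gave 37, its difference 12, the IFN-gamma difference 114 and the DMSO comparison 79. The correlations between fractions were 0.288 for IFN-gamma and 0.2381 for silvestrol, and the median silvestrol effect on polysomes of genes induced in total RNA was 0.2715, with the test turned from down to up. When induced genes were taken from the same fraction that median was -0.3952, where shared arrays alone gave -0.15 in simulation. In total RNA the same choice gave -0.0924, within the simulated range of -0.2189 to -0.0864. Simulated genes varied independently, so a deviation common to the genes of an array is not covered by these simulated values. With the replicate block the DMSO comparison gave 328. Whether the replicate numbers pair samples stays open: the differences between replicates of 15 pairs of groups correlated at -0.1325 to 0.3733, with 6 over 0.1. With an estimated correlation 15 list results passed, against 70, and fry gave 45. Under silvestrol in total RNA the 260 induced genes, at -0.1234, then had an adjusted p = 0.387 over the 2 lists, against 0.0141.

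With each array left out in turn the lone array was assumed to vary like the other groups. IFN-gamma gave 103 (without total IFN-gamma replicate 2) to 193 in total RNA and 708 (without polysomal DMSO replicate 2) to 1797 on polysomes. Silvestrol gave 4 (without total IFN-gamma plus silvestrol replicate 1) to 86 in total RNA and 157 (without polysomal IFN-gamma plus silvestrol replicate 1) to 1056 on polysomes. The differences gave 0 to 3 for silvestrol and 0 to 13 for IFN-gamma, and the DMSO comparison 1 (without polysomal DMSO replicate 2) to 174. The correlation of silvestrol effects ran from 0.3738 to 0.4518, and that of IFN-gamma effects from 0.4754 to 0.6412. The list extracellular matrix and adhesion: IFN-gamma effect in total RNA ran from -0.1924 (without total DMSO replicate 1) to 0.8268.

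Of 872 pairs of a named gene and a comparison, 239 were called. Over all alternatives 18793 values kept side and direction, 774 lost the call and 162 gained one. A further 209 changed direction with a call in neither fit, and 0 changed direction with a call. Low intensities near background limit what dim genes can show.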

Other observations

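The comparisons of IFN-gamma plus silvestrol with DMSO were tests chosen only after the result was seen.

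Cells given IFN-gamma for 24 h and silvestrol for 2 h still had interferon-response RNAs above the level of DMSO cells. Silvestrol was given for a small part of the IFN-gamma treatment. The comparison therefore cannot show how a longer exposure would act on this response. CD274 was higher by 7.26 ± 0.32 (SE) on the log2 scale in total RNA and by 7.54 ± 0.32 on polysomes (adjusted p = 1.2e-07 and 8.0e-08), IRF1 by 10.81 and 10.47, and IDO1 by 12.48 and 11.80. MCL1 was higher by 3.60 and 2.83. The MHC class I list rose in 12 of 13 members in each fraction (median 3.69 and 3.77, camera adjusted p = 9.4e-36 and 3.0e-26, and adjusted p = 0.0071 and 0.017 with an estimated correlation). In all, 268 genes were higher and 166 lower in total RNA, and 446 higher and 854 lower on polysomes.

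With silvestrol present, ribosomal protein and oxidative phosphorylation lists did not pass against DMSO on polysomes. Ribosomal proteins had a median of -0.27 (adjusted p = 0.091) and oxidative phosphorylation of -0.15 (adjusted p = 0.257), while histones were higher (median 0.61, adjusted p = 7.7e-07, and adjusted p = 0.426 with an estimated correlation) with 0 of 41 called. MYC did not pass in total RNA (0.03, adjusted p = 0.992) or on polysomes (-1.13, adjusted p = 0.178), and MITF fell on polysomes (-1.41, adjusted p = 0.027).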
